A study of Homo sapiens with 9 samples.

How the data were processed

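RNA from human macrophage cultures was sequenced after 18 h without stimulus, with interferon-gamma (IFN-gamma), or with IFN-gamma and tumour necrosis factor (TNF). There were 9 libraries, 3 in each of the 3 groups. Per the labels' protocols, polyadenylated RNA was made into libraries with a TruSeq Stranded mRNA kit and read from one end on a NovaSeq instrument. Reads were aligned with GSNAP to hg38, per the submitters' processing notes, which give no version. The counting program, its use of strand and the gene annotation are not given in the sources used here.

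Each deposited file lists whole-number read counts for 20320 Ensembl gene identifiers, per the file headers, with a width and an RPKM value for each gene. The deposited RPKM values equal count divided by width and by a library total of 26.2 to 33.0 M, per the file headers and the values themselves. The summed gene counts make up 53.6 to 58.5% of that total, and what else it holds is not given in the sources used here. For 91.0% of 20231 genes the width lay within 10% of the merged coding exons of GENCODE release 29, and for 4.1% within 10% of all merged exons. The widths are thus mostly those of coding sequence, and whether reads in untranslated regions were counted is not given in the sources used here. Symbols were matched for 20181 identifiers and not for 139. Coordinates are those of GENCODE release 29 on hg38. No row lacked a gene.

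The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr filter, TMM factors, glmQLFit and glmQLFTest). All 9 libraries shared 1 estimate of the spread, with group means as the only terms, and p-values were adjusted by the Benjamini-Hochberg method over the 11794 genes that passed the filter. The other 8526 genes were not tested. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes. TMM factors were 1.09 to 1.15 in the unstimulated libraries and 0.89 to 0.99 in the others. With library totals alone the median log2 fold change of all tested genes moved from -0.03 to -0.28 in both comparisons with the unstimulated libraries, so directions are relative to the TMM scale.

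Before the data were examined, 32 gene lists with 587 entries, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 3 tested members (31 of 32) were tested with camera in limma 3.58.1 at the preset inter-gene correlation of 0.01, and their p-values were adjusted over the lists. Named genes were taken per comparison by 3 rules. The first took the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the libraries of the groups. The next took 20 genes of the IFN-gamma and TNF pathways, called or not. The last took up to 2 called members per direction from each list, or the member with the smallest p where none was called. Genes without a symbol, XIST and genes on the Y chromosome were left out. Not every gene that these rules took is printed.

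The titles carry a code shared by 1 library of each group, written here as replicate 1, 2 or 3, and the labels do not say what it marks. Every title also carries the tag NTC, which the labels do not explain, so whether all cells were given some control treatment is not known. Libraries with the same number deviated together from their group means (correlation across genes 0.50 to 0.72 for all 9 same-number pairs, against -0.41 to -0.22 for pairs with different numbers). Deviations within a group sum to 0, so the negative values follow from the positive ones and are no separate support. By the rule fixed in advance, that every same-number correlation exceed 0.1, the numbers were taken to pair the libraries. The fit with the replicate number as a block is printed beside a result where it changes the call or moves a count by over 1.5 times. Whether the numbers stand for donors or cultures is not stated, so p-values measure the spread between these libraries.

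Alternatives were RLE factors or none, other low-count filters, a 2-fold minimum, the replicate block, only the libraries of the compared groups, DESeq2 1.42.0, estimated inter-gene correlation, fry, and leaving out libraries. Libraries were left out in the fit without the block. DESeq2 with the replicate block was added after the data were seen. The fit was tested on simulated counts with the means and spread of these libraries and 200 genes changed 1.5-, 2- or 4-fold in each of 5 simulations per comparison, on about 11649 to 11674 genes. For IFN-gamma against unstimulated, the fit without the block recovered 1.76%, 35.0% and 78.1% of genes changed 1.5-, 2- and 4-fold, and the blocked fit 30.2%, 75.0% and 95.6%. For IFN-gamma plus TNF against unstimulated these shares were 0%, 24.7% and 72.8% without the block and 37.1%, 72.4% and 92.7% with it. In IFN-gamma plus TNF against IFN-gamma they were 0.857%, 24.2% and 73.1% without it and 32.3%, 71.2% and 93.2% with it. False calls were 0% of calls without the block in each comparison. With it they were 8.17%, 7.89% and 5.82% in the same order, above or near the nominal 5%.

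Total counts per library were 14.9 to 18.5 M. A count of 0 allows up to 3 counts, and folds against a group at 0 use 3 counts over the group as a floor. Ratios over 1 to 3 counts have exact 95% intervals. Floors and intervals cover counting error only. Guanylate-binding protein and HLA genes have near-identical copies, and TAP1 lies within the annotated span of PSMB9, so how reads were divided among such genes is uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.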

Results

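The cells were hMDMs, the usual short form for human monocyte-derived macrophages, which are primary cells grown from blood monocytes. They were left unstimulated, given IFN-gamma, or given IFN-gamma and TNF together, and all were collected at 18 h. IFN-gamma is a cytokine of T and NK cells, and TNF is an inflammatory cytokine that signals through NF-kappaB. Each group had 3 libraries. Total counts were 15.3 to 16.1 M in unstimulated, 15 to 16.5 M in IFN-gamma and 14.9 to 18.5 M in IFN-gamma plus TNF libraries. No group received TNF alone, so the effect of TNF was measured only on top of IFN-gamma. Group levels below are means ± SD over 3 libraries (n = 3) in CPM, and changes are log2 fold changes with SE and edgeR adjusted p. Unless the replicate block is named, SE, adjusted p and list tests come from fits without it, which leave out the pairing.

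The first principal component, with 54.4% of the variance, separated the unstimulated libraries (-73.7 to -63.8) from those with IFN-gamma alone (17.5 to 35.9) and with both cytokines (35.6 to 46.1). The next components, with 15.9% and 15.3%, separated the replicate numbers. Within a group, libraries correlated at 0.958 to 0.968 across genes in log2 CPM, and no pair looked like the same library deposited again.

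**Figure D1:**
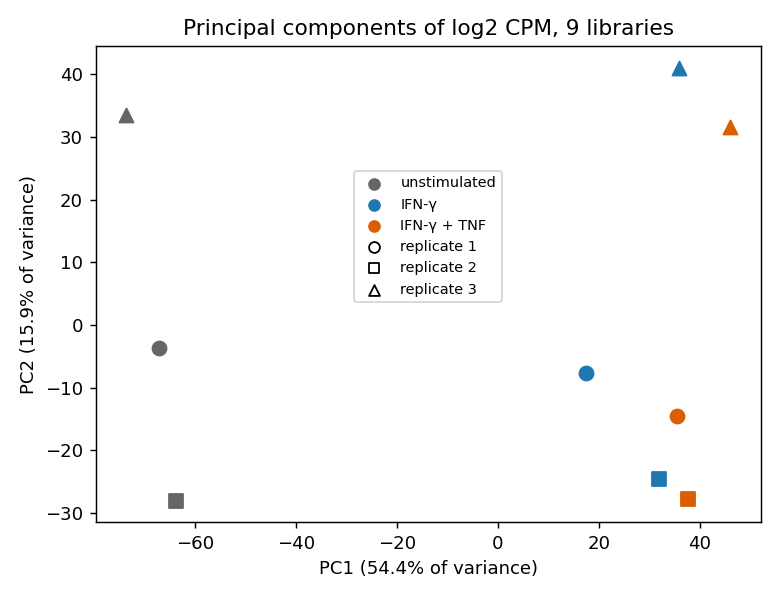
Each point is 1 library, placed by its scores on the first (x axis, 54.4% of variance) and second (y axis, 15.9%) principal components of log2 CPM. Colour marks the group and shape the replicate number. Unstimulated libraries lie at -63.8 or below on the x axis and all stimulated libraries at 17.5 or above.

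The comparison of IFN-gamma with unstimulated macrophages asks which genes respond to this cytokine at 18 h. The largest rises were in 3 chemokine genes and IDO1. CXCL9, CXCL10 and CXCL11, neighbours on chromosome 4 (hg38, 76001275 to 76007488, 76021117 to 76023497 and 76033682 to 76041415), encode ligands of CXCR3, a chemokine receptor of T cells. CXCL11 (ENSG00000169248) had 0 counts in the unstimulated group and 176 ± 153 CPM with IFN-gamma, at least 3120-fold higher against a floor of 3 counts over the group. CXCL9 (ENSG00000138755) had 2 unstimulated counts and 764 ± 382 CPM with IFN-gamma, a ratio of 20300 (exact 95% counting interval 5620 to 168000). CXCL10 went from 0.227 ± 0.199 to 1050 ± 590 CPM (12.14 ± 0.73 SE, adjusted p = 1.2e-05). IDO1, which starts tryptophan breakdown to kynurenine, rose from 0.131 ± 0.0643 to 1670 ± 727 CPM (13.55 ± 0.65 SE, adjusted p = 4.7e-06). The transcription factor gene ETV7 rose by 9.19 ± 0.54 SE to 81.4 ± 23.7 CPM, and RSPO3, a Wnt signal enhancer, was at least 92.5-fold higher at 5.23 ± 5.07 CPM. Without IFN-gamma replicate 3 the fitted log2 change of RSPO3 went from 9.38 to 8.24 and that of CXCL11 from 14.46 to 13.48. Among the largest falls were MYB, a transcription factor of blood progenitors (9.95 ± 5.46 to 0.135 ± 0.116 CPM, log2 change -6.12 ± 0.77), the sphingosine receptor gene S1PR1 (-5.71 ± 0.72), the kinase gene ALK (7.32 ± 9.33 CPM unstimulated, -5.68 ± 1.17, and -3.76 without unstimulated replicate 3) and VCAN, which encodes a matrix proteoglycan (1280 ± 1000 to 65.0 ± 21.2 CPM, -4.30 ± 0.58). Without unstimulated replicate 3 the values for VCAN and S1PR1 were -3.47 and -5.10. PID1 (-5.18 ± 1.17, adjusted p = 0.015) and F13A1, the coagulation factor XIII A chain (-4.13 ± 1.01, adjusted p = 0.022), also fell. Their calls were lost when 1 library was left out, PID1 without IFN-gamma replicate 1 or 3 (adjusted p 0.05 to 0.056) and F13A1 without IFN-gamma replicate 1 or 2 or unstimulated replicate 3 (0.064 to 0.078), the last with a log2 change of -2.41. These omissions used the fit without the block. With the block and all libraries PID1 was at -5.29 ± 0.58 and F13A1 at -3.63 ± 0.32 (adjusted p = 4.7e-05 and 8.4e-06).

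Genes of interferon signalling rose together. Of 20 tested IFN-gamma signalling and response factor genes, 15 rose and 1 fell (18 and 1 adjusted over the list alone), with camera adjusted p = 2.2e-38. IRF1, which encodes a transcription factor of the interferon response, rose from 27.3 ± 4.18 to 515 ± 39.7 CPM (4.24 ± 0.17 SE, adjusted p = 3e-06), and BATF2 rose by 5.15 ± 0.40. The receptor chain gene IFNGR1 was the member that fell, from 389 ± 111 to 127 ± 28.5 CPM (-1.61 ± 0.24, adjusted p = 0.0021). IFNGR2, which encodes the other chain, was at 249 ± 13.5 and 375 ± 100 CPM (adjusted p = 0.059, and 0.0092 with the replicate block). All 8 tested guanylate-binding proteins and related GTPases, which act against intracellular microbes, rose (8 adjusted over the list alone, camera adjusted p = 4.6e-44), including GBP5 (7.89 ± 2.77 to 2360 ± 468 CPM) and GBP4 (8.52 ± 0.36 SE). All 27 type I interferon-stimulated genes rose (27 adjusted over the list alone, median 3.09, camera adjusted p = 1.2e-92), with IFI27 at 8.70 ± 0.91 and IFI44L at 7.57 ± 0.36. These calls hold with an estimated correlation (adjusted p = 0.0013, 0.00077 and 0.0013 for the signalling, GTPase and type I lists).

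Antigen presentation genes rose as well. In the MHC class I list 17 of 21 genes rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 1.3e-34, and p = 0.01 with an estimated correlation). TAP1, which carries peptides into the endoplasmic reticulum, rose from 117 ± 18.0 to 2350 ± 401 CPM, and the immunoproteasome gene PSMB9 rose by 3.44 ± 0.21. Of 16 MHC class II genes 7 rose (8 adjusted over the list alone, 15 with the replicate block, camera adjusted p = 4.5e-06). That list's call was lost with an estimated correlation (adjusted p = 0.37). CIITA, the master regulator of class II genes, rose from 44.6 ± 20.8 to 228 ± 43.4 CPM (2.35 ± 0.34, adjusted p = 0.0018), and HLA-DOA rose by 3.05 ± 0.50.

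Chemokine, cytokine and NF-kappaB lists moved in the same direction. Of 23 chemokine genes 8 rose (9 adjusted over the list alone, 15 up and 1 down with the block), of 20 inflammatory cytokine genes 9 rose (12 adjusted over the list alone, 12 up and 1 down with the block), and of 31 NF-kappaB pathway and TNF-induced genes 12 rose (14 adjusted over the list alone, 23 with the block). Camera gave adjusted p = 2e-08, 4.8e-05 and 5.1e-08, and these calls were lost with an estimated correlation (adjusted p = 0.19, 0.19 and 0.33), while the chemokine list had adjusted p = 0.047 with the block as well. The cytokine gene IL27 rose by 5.35 ± 1.08 (adjusted p = 0.0094). IL18BP, which encodes a binding protein that neutralises interleukin-18, rose by 3.79 ± 0.46 to 238 ± 98.2 CPM. In the NF-kappaB list, CD40, a costimulatory receptor gene, rose by 2.89 ± 0.34, TNFAIP6 by 3.99 ± 0.63, and TNFAIP3, which encodes the NF-kappaB inhibitor A20, from 49.9 ± 13.5 to 200 ± 52.9 CPM. TNF itself was at 2.34 ± 1.23 and 30.2 ± 24.1 CPM (3.69 ± 1.03, adjusted p = 0.036), and this call was lost without any 1 of 5 libraries, the exception being IFN-gamma replicate 1 (adjusted p 0.075 to 0.11). With the block and all libraries TNF rose by 3.48 ± 0.39 (adjusted p = 5.9e-05). NFKBIA (0.75 ± 0.29), BIRC3 (1.61 ± 0.70) and TRAF1 (2.05 ± 0.89) did not pass the threshold (adjusted p = 0.11, 0.15 and 0.15). With the replicate block their adjusted p was 0.0051, 0.00038 and 0.0063. The type 2 TNF receptor gene TNFRSF1B rose by 0.83 ± 0.13 (adjusted p = 0.0034), while TNFRSF1A was at 190 ± 33.5 and 161 ± 24.3 CPM (adjusted p = 0.38).

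Cell death and host defence lists also contained called genes. Of 18 death receptor and necroptosis genes 6 rose (10 adjusted over the list alone and 10 with the block, camera adjusted p = 0.0056, p = 0.09 with an estimated correlation), with ZBP1, a nucleic acid sensor, at 3.81 ± 0.43. CASP8 was at 26.3 ± 2.95 and 34.9 ± 2.62 CPM (adjusted p = 0.093, and 0.016 with the block). Of 15 inflammasome and pyroptosis genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, 10 and 2 with the block, camera adjusted p = 0.0058, p = 0.26 with an estimated correlation), and this list call was lost without unstimulated replicate 2 (adjusted p = 0.059). The DNA sensor gene AIM2 rose by 3.92 ± 0.48. Of 19 antimicrobial metabolism and oxidant genes 13 rose (13 adjusted over the list alone, median 2.81, camera adjusted p = 1.1e-29, p = 0.016 with an estimated correlation). One was ACOD1, which makes itaconate, with 3 unstimulated counts and a ratio of 659 (exact 95% counting interval 225 to 3200). NOS2, the inducible nitric oxide synthase gene, had 0 counts in all 9 libraries, which allows up to 0.162 to 0.201 CPM per library. Among 17 negative regulators and checkpoint ligands 11 rose and 1 fell (11 and 1 adjusted over the list alone, 11 and 2 with the block, camera adjusted p = 2.4e-08, p = 0.081 with an estimated correlation). CD274, which encodes PD-L1, rose from 11 ± 3.86 to 258 ± 74.9 CPM, and SOCS2 fell by 2.64 on the log2 scale. SOCS1, a feedback inhibitor of JAK kinases, was at 0.946 ± 1.06 and 13.4 ± 14.3 CPM (3.82 ± 1.01, adjusted p = 0.03), a call lost without unstimulated replicate 1 or 2 or IFN-gamma replicate 3 (adjusted p 0.084 to 0.1). With the block and all libraries SOCS1 rose by 3.77 ± 0.32 (adjusted p = 7.0e-06). Of 21 complement and Fc receptor genes 8 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00015, p = 0.19 with an estimated correlation), with the C1 inhibitor gene SERPING1 up from 6.82 ± 5.40 to 642 ± 168 CPM.

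Genes of cholesterol synthesis and of cell division fell. In the cholesterol synthesis and uptake list 16 of 20 genes fell and 0 rose (17 and 0 adjusted over the list alone, median -1.47, camera adjusted p = 4.4e-19, p = 0.053 with an estimated correlation and 0.011 with the block as well). DHCR7, the last enzyme of one branch of the pathway, fell from 190 ± 52.7 to 19.8 ± 7.77 CPM (-3.27 ± 0.38). Of 24 proliferation genes 21 fell (23 adjusted over the list alone, median -2.25, camera adjusted p = 7e-14, p = 0.19 with an estimated correlation). TYMS, the thymidylate synthase gene, fell from 52.8 ± 30.8 to 5.55 ± 2.03 CPM. Markers of granulocytes moved with these genes. Of 11 neutrophil and mast cell markers 4 fell (4 adjusted over the list alone, 8 with the block, camera adjusted p = 0.012, p = 0.1 with an estimated correlation), among them ELANE (3.64 ± 3.10 to 0.361 ± 0.105 CPM) and CAMP (4.23 ± 2.34 to 0.586 ± 0.405 CPM). Each of those calls was lost without some single library. For ELANE these were any IFN-gamma library or unstimulated replicate 3 (adjusted p 0.072 to 0.1), and for CAMP unstimulated replicate 1 or IFN-gamma replicate 2 or 3 (0.06 to 0.07). With the block and all libraries ELANE and CAMP had adjusted p = 5.9e-04 and 5.0e-04. Only 4 of 19 T and NK cell markers were tested and 2 rose (3 adjusted over the list alone), among them CD7, from 0 counts to 1.11 ± 0.39 CPM, at least 19.6-fold. That list passed camera (adjusted p = 0.0056, p = 0.18 with an estimated correlation), but not without any 1 of 5 libraries, all but unstimulated replicate 3 (0.065 to 0.23).

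The other lists did not pass camera. Among 23 alternatively activated macrophage genes 3 rose and 6 fell (3 and 9 adjusted over the list alone, 4 and 11 with the block, camera adjusted p = 0.071, 0.0027 with the block, and p = 0.31 with the block and an estimated correlation). CLEC10A rose by 1.99 ± 0.22 and SELENOP fell by 2.38. Among 20 macrophage identity genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, 6 and 3 with the block), and the member that fell was CD14, a lipopolysaccharide co-receptor (1090 ± 422 to 198 ± 66.3 CPM, -2.46 ± 0.42). In the cholesterol efflux and lipid handling list 1 of 15 rose and 3 fell (1 and 4 adjusted over the list alone, 3 and 6 with the block), with ABCG1, a cholesterol exporter, at -3.04 ± 0.37. Camera gave adjusted p = 0.31, and 0.021 with the block, a call lost with an estimated correlation as well (adjusted p = 0.11). Glycolysis genes split, 3 of 21 up and 4 down (3 and 4 adjusted over the list alone), with HK3 at 1.10 ± 0.16 and PFKM at -0.83 ± 0.19. Calls up and down were 4 and 1 of 14 BCL2 family genes (4 and 1 adjusted over the list alone), 4 and 0 of 28 nuclear-encoded respiratory chain genes (3 and 0, 9 and 0 with the block), 3 and 1 of 20 integrated stress response genes (3 and 1, 7 and 4 with the block), 2 and 0 of 18 p53 targets (2 and 0, 6 and 1 with the block) and 1 and 0 of 11 heat shock genes (1 and 0, 3 and 0 with the block). The p53 target CDKN1A, an inhibitor of the cell cycle, rose from 129 ± 8.46 to 418 ± 144 CPM. None of 13 mitochondrially encoded mRNAs, 3 B and plasma cell markers or 4 platelet markers was called (0 adjusted over the list alone in each, while the block called 1, 0 and 2). MT-ND1 had adjusted p = 0.19 and PPBP adjusted p = 0.1, and 0.022 and 0.016 with the block. Calls up and down were 1 and 1 of 11 dendritic cell markers (1 and 1 adjusted over the list alone, 5 and 2 with the block), and 0 and 2 of 5 fibroblast and endothelial markers (0 and 2 adjusted over the list alone), including VWF (59.6 ± 27.6 to 3.95 ± 0.712 CPM). Of 9 red blood cell markers 1 was tested, HBB (-1.80 ± 0.56, adjusted p = 0.053, called as 1 lower adjusted over the list alone, and 0.018 with the block).

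In all, 1176 genes were higher and 967 lower with IFN-gamma (18.2% of 11794 tested), 565 and 585 of them by at least 2-fold. With the replicate block the counts were 2108 and 1970, and all 2143 genes called without it were called. With library totals alone the split was 706 and 2017, 25.9% higher against 54.9%. The lower count was 562 without IFN-gamma replicate 2, 591 without unstimulated replicate 3 and 548 without IFN-gamma replicate 3. Camera called 17 lists, 5 of them with an estimated correlation. Other splits of the 6 libraries, which mix both groups on each side, gave up to 20 lists.

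**Figure D2:**
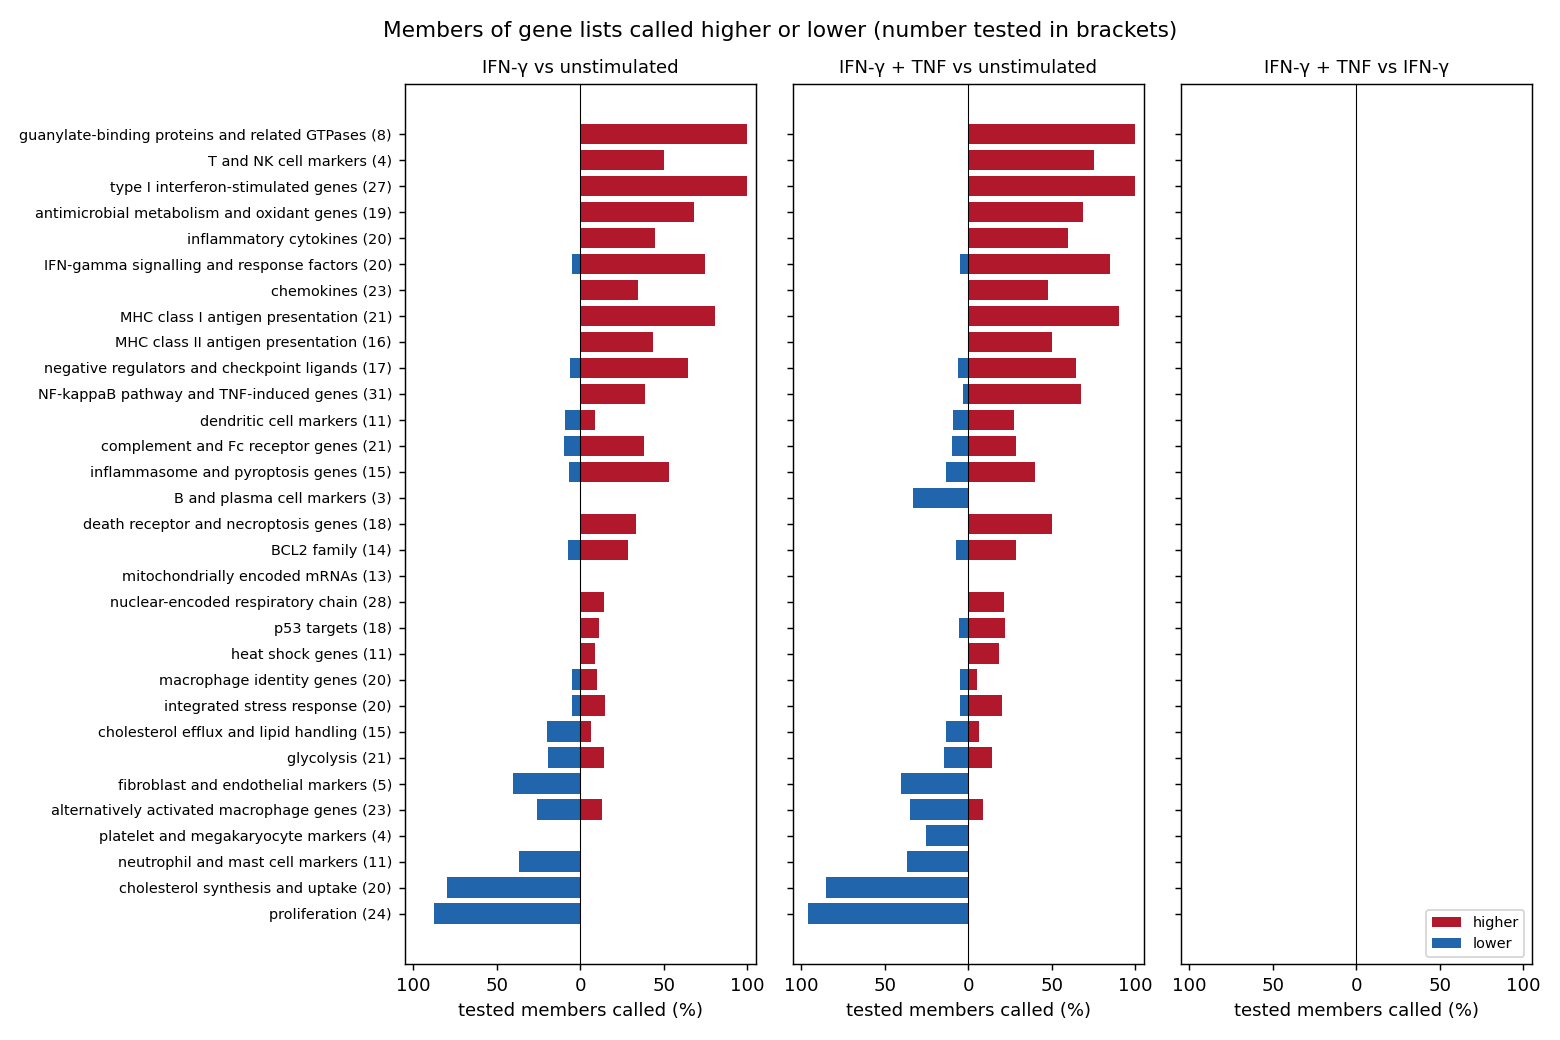
Bars give the percentage of each list's tested members called higher (red, to the right) or lower (blue, to the left) at an edgeR adjusted p under 0.05, with the number tested in brackets. The panels show IFN-gamma against unstimulated, both cytokines against unstimulated, and both against IFN-gamma, where 0 genes were called. All calls shown are from the fit without the replicate block.

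IFN-gamma with TNF, set against unstimulated macrophages, gave changes in many of the genes above. CXCL9 reached 1320 ± 604 CPM, a ratio of 33800 over its 2 unstimulated counts (exact 95% counting interval 9360 to 279000). CXCL11 was at least 3750-fold higher at 227 ± 163 CPM, IDO1 rose by 14.21 ± 0.66 to 2640 ± 1110 CPM, CXCL10 rose by 12.47 ± 0.73, and RSPO3 was at least 134-fold higher. UBD, which encodes a ubiquitin-like modifier, rose from 0.095 ± 0.0871 to 183 ± 91.1 CPM (10.81 ± 0.97, adjusted p = 0.00012). Among the 6 largest falls were ALK, with 1 count left in this group and 335-fold lower (exact 95% counting interval 59.7 to 13300, log2 change -7.94 and -6.02 without unstimulated replicate 3), the lectin gene LGALS12 (-6.56 ± 0.76), P2RY8 (-5.97 ± 0.85), F13A1 (-5.87 ± 1.12, and -4.14 without unstimulated replicate 3), TMEM37 (-5.82 ± 0.63) and PID1 (-5.56 ± 1.20). P2RY8 was at -5.23 without unstimulated replicate 3, and without replicate 3 of both cytokines RSPO3 went from 10 to 8.94 and CXCL11 from 14.82 to 14.18. IRF1 rose by 4.29 ± 0.18, GBP5 by 8.41 ± 0.42, CIITA by 2.18 ± 0.33 and CD274 by 4.70 ± 0.35. IFNGR1 fell by 1.59 on the log2 scale, and IFNGR2 rose by 0.81 ± 0.19 to 436 ± 64.1 CPM (adjusted p = 0.014). TNFRSF1B rose by 0.91 ± 0.13, and TNFRSF1A was at 149 ± 19.8 CPM (adjusted p = 0.16, and 0.011 with the block). CASP8 was at 34.4 ± 5.56 CPM (adjusted p = 0.09, and 0.019 with the block).

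Interferon and antigen presentation lists rose here too. The genes that rose were 17 of 20 for IFN-gamma signalling (18 adjusted over the list alone, 1 fell), 8 of 8 GTPases (8 adjusted over the list alone), 27 of 27 type I interferon-stimulated genes (27 adjusted over the list alone), 19 of 21 MHC class I genes (19 adjusted over the list alone) and 13 of 19 antimicrobial genes (14 adjusted over the list alone, 15 up and 1 down with the block). Their camera calls held with an estimated correlation (adjusted p = 0.0015, 0.0013, 0.0015, 0.018 and 0.023). Of 31 NF-kappaB pathway and TNF-induced genes 21 rose and 1 fell (24 and 1 adjusted over the list alone, camera adjusted p = 1.3e-10, p = 0.25 with an estimated correlation). Its members included TNFAIP6 (2.02 ± 0.418 to 102 ± 63.2 CPM, 5.66 ± 0.66), TNFAIP3 (2.50 ± 0.24), BIRC3 (2.42 ± 0.72, adjusted p = 0.036) and NFKBIA (0.92 ± 0.30, adjusted p = 0.048). The BIRC3 call was lost without any 1 of 5 libraries (0.051 to 0.11) and the NFKBIA call likewise (0.086 to 0.14), unstimulated replicate 2 being the exception for each. Both were called with the block and all libraries. TRAF1 was at 45.1 ± 18.8 CPM (2.77 ± 0.90, adjusted p = 0.052, and 0.00045 with the block). Of 23 chemokine genes 11 rose (15 adjusted over the list alone, 17 with the block) and of 20 inflammatory cytokine genes 12 rose (13 up and 1 down adjusted over the list alone, 13 and 2 with the block), with camera adjusted p = 1.2e-09 and 2.9e-06, lost with an estimated correlation (adjusted p = 0.19 and 0.14), with 0.041 for chemokines with the block as well. EBI3, a subunit of interleukin-27, reached 5.12 ± 5.38 CPM from 3 unstimulated counts, a ratio of 83.4 (exact 95% counting interval 28.2 to 408). TNF and SOCS1 were called (adjusted p = 0.02 and 0.028), but not without unstimulated replicate 1 or 2 or replicate 3 of the stimulated group (0.061 to 0.074 for TNF and 0.078 to 0.093 for SOCS1). These 2 genes were also called with the block and all libraries.

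Lists that fell after IFN-gamma alone fell with both cytokines. Among cholesterol synthesis and uptake genes 17 of 20 fell (17 adjusted over the list alone, median -1.37, camera adjusted p = 3.3e-15, p = 0.074 with an estimated correlation and 0.014 with the block as well), with DHCR7 at -3.43 ± 0.38. Among proliferation genes 23 of 24 fell (23 adjusted over the list alone, median -2.47, camera adjusted p = 3.7e-13, p = 0.21 with an estimated correlation), with TYMS at -3.42 ± 0.49. Neutrophil and mast cell markers moved with them, 4 of 11 lower (6 adjusted over the list alone, 8 with the block, camera adjusted p = 0.011, p = 0.097 with an estimated correlation). Alternatively activated macrophage genes passed camera (2 of 23 rose and 8 fell, 3 and 13 adjusted over the list alone, 3 and 17 with the block, adjusted p = 0.0014), a call lost with an estimated correlation (adjusted p = 0.25). F13A1 and SELENOP (64.2 ± 40.9 to 10.1 ± 1.47 CPM) were its called members with the largest falls.

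Other lists past the camera threshold had their calls lost with an estimated correlation. They were MHC class II (8 of 16 up, 9 adjusted over the list alone, 14 with the block, p = 0.4 with an estimated correlation), death receptor genes (9 of 18 up, 11 adjusted over the list alone, 11 up and 1 down with the block, p = 0.065), inflammasome genes (6 up and 2 down of 15, 8 and 3 adjusted over the list alone, 10 and 4 with the block, p = 0.34), negative regulators (11 up and 1 down of 17, 11 and 1 adjusted over the list alone, 11 and 2 with the block, p = 0.097), complement and Fc receptor genes (6 up and 2 down of 21, 8 and 2 adjusted over the list alone, 11 and 4 with the block, p = 0.25), T and NK cell markers (3 of 4 up, 3 adjusted over the list alone, p = 0.21) and the nuclear-encoded respiratory chain (6 of 28 up, 6 adjusted over the list alone, 14 with the block, p = 0.59). Camera for the respiratory chain gave adjusted p = 0.044, and 0.074 with the block. The inflammasome call was also lost without unstimulated replicate 2 (0.16), the respiratory chain call without unstimulated replicate 1 or 2 or stimulated replicate 2 or 3 (0.051 to 0.13), and the T and NK call without any library except unstimulated replicate 3 (0.066 to 0.25). Cholesterol efflux genes (1 up and 2 down of 15, 1 and 2 adjusted over the list alone, 4 and 6 with the block, adjusted p = 0.33) and dendritic cell markers (3 up and 1 down of 11, 3 and 1 adjusted over the list alone, 7 and 1 with the block, adjusted p = 0.17) passed only with the block (0.049 and 0.016), and not with an estimated correlation as well (adjusted p = 0.14 and 0.12). LAMP3, a marker of mature dendritic cells, rose from 1.95 ± 1.5 to 30.2 ± 7.87 CPM, and FCER1A fell to 3 counts in the group, 19.4-fold lower (exact 95% counting interval 6.35 to 96.3). Of 13 mitochondrially encoded mRNAs 0 were called (0 adjusted over the list alone), and 7 were called higher with the block, among them MT-ND6 (adjusted p = 0.16, and 0.024 with the block).

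In all, 1524 genes were higher and 1356 lower with both cytokines than without (24.4% of those tested), 717 and 806 by at least 2-fold. With the block 2494 and 2418 genes were called, including all 2880 called without it, and with library totals alone the split was 890 and 2686 (24.9% higher against 52.9%). Camera called 19 lists, 5 with an estimated correlation, and other splits of the 6 libraries, each mixing both groups, gave up to 21.

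The 2 comparisons with unstimulated libraries shared 1097 genes called higher and 877 called lower, 1974 in all, and 0 genes were called in opposite directions. Both stimulated groups received IFN-gamma, so a large overlap in the same direction follows from the design. Independent lists of these sizes would share 152 and 111. In 40 simulations of unchanged groups, which keep the differences between replicate numbers, 0 genes were shared. This fit made 0 false calls in the simulated counts, so that 0 was foreseeable. Neither reference tests whether the responses are more alike than shared IFN-gamma would give. The log2 fold changes correlated at 0.96 across genes, against 0.487 in the simulations, and genes are not independent replicates. Their covariance was 1.05, against a simulated 0.0297 from the shared unstimulated libraries, a difference of 1.02. For the overlap, part of the excess over independent lists may come from these 3 libraries, too few to divide. With the block 3673 genes were shared and 1 was called in opposite directions, and without IFN-gamma replicate 3 the shared count was 1305.

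**Figure D3:**
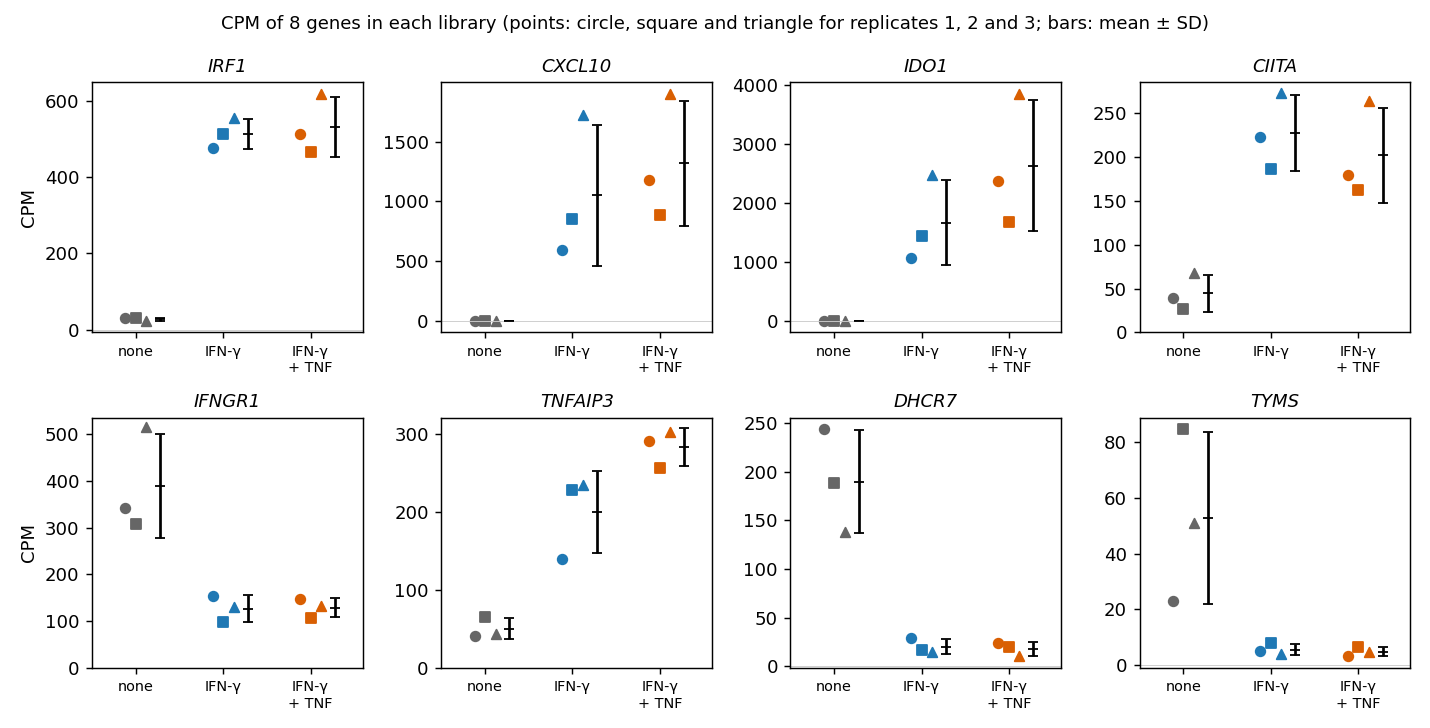
CPM (linear y axes) of 8 genes in each library, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD of each group (n = 3). IRF1, CXCL10, IDO1, CIITA and TNFAIP3 were higher and IFNGR1, DHCR7 and TYMS lower in both stimulated groups, and IDO1 was at 1670 ± 727 CPM with IFN-gamma and 2640 ± 1110 CPM with both cytokines.

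The comparison of both cytokines with IFN-gamma alone asks what TNF adds. Without the replicate block, no gene passed the threshold with edgeR. At an unadjusted p under 0.05 there were 228 genes (1.93% of 11794). DESeq2 without the block also called 0 genes, with 232 at that unadjusted level. Of the genes called with IFN-gamma against unstimulated, 0 changed again in these fits. The numbers were taken to pair the libraries, and these fits leave that pairing out. With the replicate block, edgeR called 2 genes, both higher with TNF. One of them, chosen after its values were seen, was CCL1, which encodes a monocyte-attracting chemokine (19.4 ± 23.7 to 42.0 ± 44.6 CPM, blocked log2 change 1.28 ± 0.15, blocked adjusted p = 0.038). It was higher with TNF in 3 of 3 pairs of libraries with the same number. The blocked fit had 892 genes at an unadjusted p under 0.05 (7.56%). DESeq2 with the block, added after the data were seen, called 37 genes higher and 25 lower, including those 2.

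Of 31 NF-kappaB pathway and TNF-induced genes 28 had a log2 change above 0 with TNF, and none passed the test with edgeR. TNFAIP3 was at 200 ± 52.9 and 283 ± 24.3 CPM (0.50 ± 0.23), BIRC3 at 39.9 ± 27.6 and 70.3 ± 34.0 CPM (0.82 ± 0.68), TRAF1 at 27.5 ± 20.5 and 45.1 ± 18.8 CPM (0.71 ± 0.84), and TNFAIP6, the NF-kappaB list member with the smallest p, at 32.1 ± 21.2 and 102 ± 63.2 CPM (1.67 ± 0.54). Blocked adjusted p for these genes was 0.51, 0.24, 0.63 and 0.14, each was higher with TNF in 3 of 3 pairs of libraries with the same number, and DESeq2 with the block called BIRC3 (1 ± 0.23, adjusted p = 0.0042). NFKBIA, at 248 ± 83.4 and 279 ± 23.3 CPM, had a log2 change of 0.17 ± 0.29, and TNF one of 0.38 ± 0.89. Among IFN-gamma targets, IRF1 was at 515 ± 39.7 and 533 ± 78.7 CPM (0.05 ± 0.15), GBP5 at 0.19 ± 0.30, CIITA at -0.17 ± 0.32, CD274 at 0.14 ± 0.30 and SOCS1 at -0.17 ± 0.86. The chemokine genes CXCL9 and CXCL10 had log2 changes of 0.79 ± 0.43 and 0.33 ± 0.42, and IDO1 one of 0.66 ± 0.35. IDO1 was also higher with TNF in 3 of 3 such pairs, and DESeq2 with the block called it (0.66 ± 0.17, adjusted p = 0.03). The receptor genes IFNGR1 (0.02 ± 0.23), IFNGR2 (0.22 ± 0.19), TNFRSF1A (-0.12 ± 0.17) and TNFRSF1B (0.08 ± 0.13) and CASP8 (-0.02 ± 0.15) did not pass the test. CXCL10, CD274, IFNGR2 and TNFRSF1B were also higher with TNF in 3 of 3 same-number pairs, and CIITA and TNFRSF1A were lower in 3 of 3. IRF1, GBP5, CXCL9, SOCS1, IFNGR1, CASP8, NFKBIA and TNF ran in both directions. Agreement in 3 of 3 pairs is weak evidence for a gene, since an exact two-sided sign test over 3 pairs cannot go below p = 0.25. The share of all tested genes with such agreement was not counted.

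Camera called 6 lists with TNF. NF-kappaB pathway genes (median 0.31, adjusted p = 2.5e-07), chemokines (0.40, 0.00039), inflammatory cytokines (0.27, 0.0005), type I interferon-stimulated genes (0.18, 0.00034) and antimicrobial genes (0.12, 0.013) ranked toward higher values, and alternatively activated macrophage genes toward lower values (median -0.43, 6.8e-08). With an estimated correlation these calls were lost (adjusted p = 0.63, 0.63, 0.61, 0.63, 0.66 and 0.52), and fry called 0 lists. Without the block no member of any list was called (0 adjusted over the list alone in each list). With the block 1 chemokine gene was called, CCL1. Adjusted over the list alone, the block called 10 of 23 alternatively activated genes lower, and 5 chemokine, 4 cytokine, 3 antimicrobial, 3 dendritic cell and 2 NF-kappaB genes higher. It called 1 higher and 1 lower in the complement and platelet lists, 1 lower in the macrophage identity list and 1 higher in the cholesterol efflux list. In the alternatively activated list TREM2, a lipid-sensing receptor gene, had the smallest p, at 374 ± 35.3 and 250 ± 4.29 CPM. Without IFN-gamma replicate 1 the NF-kappaB call was lost (adjusted p = 0.42), as were the other 4 calls toward higher values, and without IFN-gamma replicate 3 the number of lists was 11. The type I call was lost without IFN-gamma replicate 1 or replicate 2 of both cytokines (0.13 to 0.31), and the chemokine call without IFN-gamma replicate 1 or replicate 3 of both cytokines (0.15 to 0.91). The cytokine (0.051 to 0.25) and antimicrobial (0.091 to 0.94) calls were lost without IFN-gamma replicate 1 or 2 or replicate 3 of both cytokines. Other splits of the 6 libraries, each mixing both groups, gave up to 17 lists. With the block, macrophage identity genes (median -0.14, adjusted p = 0.0055) and proliferation genes (-0.15, 0.017) also passed toward lower values and dendritic cell markers (0.27, 0.001) toward higher values. These calls were lost with the block and an estimated correlation (adjusted p = 0.39, 0.69 and 0.2).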

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

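DESeq2 with the replicate block was chosen after seeing the data. The cause of each move below was not tested, except that fits with fewer libraries have fewer degrees of freedom and a 2-fold minimum can only lower a count. No call of a named gene or list turned into a call in the other direction. RLE factors, other low-count filters, DESeq2 without a block and the 6-library fits left every count of genes within 1.5 times. Counts below run higher and lower for IFN-gamma against unstimulated, then higher and lower for both cytokines against unstimulated. They were 706, 2017, 890 and 2686 with no composition factors, 565, 585, 717 and 806 (1073 shared) at 2-fold or more, and 2108, 1970, 2494 and 2418 (3673 shared) with the replicate block. DESeq2 with the block gave 2071, 1787, 2372 and 2200 (3475 shared). For both cytokines against IFN-gamma, where 0 genes were called, the block gave 2 higher, and 2 IFN-gamma responsive genes changed again. DESeq2 with the block gave 37 and 25, and 49 changed again. Leaving out 1 library, or all 3 with 1 number, gave 500 to 1020, 184 to 772, 715 to 1328 and 475 to 1134, with 658 to 1649 shared and 0 genes throughout for TNF addition. Lists past the threshold numbered 17, 19 and 6 in the 3 comparisons, 5, 5 and 0 with an estimated correlation, and 0 in the last with fry. Leaving out libraries gave 16 to 19, 16 to 21 and 4 to 11 lists. Of 82 and 91 named genes called against unstimulated, 24 and 22 lost the call in at least 1 omission of a single library. These omissions used the fit without the block, and with the block and all libraries each of these genes was called. Over all alternatives, named genes kept their side of the threshold in 3813 of their tests, lost it in 421 and gained it in 57. Lists kept it in 909, lost it in 71 and gained it in 43. The replicate block changed no other call of a named gene or list than those given or counted with the results. Depth limits low genes, such as NOS2 at 0 counts, and the spread between numbers limits the fits without the block.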

Other observations

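The tests of scaling, of granulocytes, of shared libraries and of other splits were chosen after the results were seen. Predictions for the tests of precision and of a single weak library were written before the outcomes of those tests were seen. The patterns they address are themselves results of these data, so those tests were not chosen blind to the data.

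Genes called between both cytokines and IFN-gamma by DESeq2 with the replicate block were examined after the data were seen, outside the rule for named genes. Those higher with TNF included the metalloproteinase genes MMP7 (1.07 ± 0.17 SE, adjusted p = 1.2e-06) and MMP12 (0.99 ± 0.18, 5.6e-05), the cystine transporter gene SLC7A11 (0.94 ± 0.17, 9.3e-05), the cholesterol exporter gene ABCG1 (1.07 ± 0.17, 1.7e-06), IL1A (1.44 ± 0.31, 0.002) and BIRC3 (1 ± 0.23, 0.0042). Among those lower were the scavenger receptor gene CD163 (-0.59 ± 0.16, 0.04), the lysosomal protease gene CTSD (-0.49 ± 0.13, 0.041), TREM2 (-0.57 ± 0.14, 0.0088), RNASE1 (-1.01 ± 0.21, 0.0015) and F13A1 (-2.11 ± 0.53, 0.022). The edgeR fit with the block called 2 of these 62 genes and the fits without it 0. DESeq2 with the block was not run on the simulated counts, so its share of false calls is not known. It gave no adjusted p for 1372 genes in this comparison, so its adjustment covered fewer genes than that of edgeR.

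The count of 0 genes between both cytokines and IFN-gamma in the fit without the block may reflect limited precision. In simulated data with this spread, edgeR without the block called 24.2% of genes changed 2-fold and 73.1% of those changed 4-fold in this comparison, so most 2-fold changes would be missed. With the block 71.2% of 2-fold changes were called in the simulations, and the data gave 2 genes. Each simulation held 200 changed genes. With fewer changed genes the adjusted threshold is stricter, so the shares recovered in these data may be lower. Whether TNF changed many genes by less than 2-fold stays open.

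The lower proliferation genes after IFN-gamma were tested against the scaling of the libraries. The list median was -2.24 or lower under TMM, RLE and no factors, while the median of all genes moved by no more than -0.28. This argues against the choice among these scalings as the whole cause. A scaling moves all genes by about the same amount, so the outcome followed from that small shift. The lower granulocyte markers could come from a smaller share of admixed granulocytes or their precursors. Their markers would then fall by a common amount, if a single cell type carried them all and macrophages expressed none. The 11 tested markers moved apart by more than their errors (Cochran's Q over n = 11 markers, p = 1.2e-12, and 3.7e-06 without CSF3R, which macrophages may also express, with the errors taken as independent). With the block they ran from ELANE at -3.13 ± 0.49 and CAMP at -2.85 ± 0.44 to CSF3R at -0.48 ± 0.13 and FCGR3B at 0.42 ± 0.60. MMP8 (-1.47 ± 0.15), MPO (-1.26 ± 0.15) and CEACAM8 (-1.06 ± 0.27) fell by similar amounts. Unstimulated levels were low (MMP8 40.1, CEACAM8 18.2, MPO 16.8, CAMP 4.23, ELANE 3.64 and FCGR3B 0.76 CPM, with CSF3R at 199 CPM). The list mixes neutrophil and mast cell markers, and expression in macrophages would also part them, so the test cannot decide. A smaller share of admixed cells, a change in the macrophages and the loss of precursors of several stages stay open.

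Across genes, TNF addition ran weakly in the direction of the IFN-gamma response, but not in every list. With TNF added, median log2 changes of lists that rose after IFN-gamma ran from 0.40 for chemokines to -0.14 for negative regulators. They were 0.05 for IFN-gamma signalling, 0.03 for MHC class I, -0.03 for MHC class II and 0.18 for type I interferon-stimulated genes. ABCG1, which fell after IFN-gamma, was higher with TNF in DESeq2 with the block (1.07 ± 0.17). Across 11794 genes the log2 changes for both cytokines against IFN-gamma correlated at 0.17 with those for IFN-gamma against unstimulated. IFN-gamma libraries enter these with opposite signs, so sharing them pushes the covariance below 0 (-0.0315 in 40 simulations of unchanged groups), yet it was 0.0524, which argues against the shared libraries as its source. A single IFN-gamma library with a weak response could also give it, but with the IFN-gamma effect taken from the other numbers, over the 11084 genes of at least 1 CPM, the slope was above 0 in 3 of 3 numbers (0.14, 0.03 and 0.08, the smallest 7.94 times its error from a jackknife over 27 blocks of genes by chromosome). That error covers genes and not cultures, and an exact two-sided sign test over 3 pairs cannot go below p = 0.25, so a hypothesis that TNF extends the IFN-gamma programme stays untested beyond these libraries, as does a difference in the cytokine dose between cultures.

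With 3 libraries against 3 there are 10 splits, so the share of splits as large is never under 0.1. For genes, IFN-gamma against unstimulated gave 2143 and the highest other split 0 (1 of 10 as large), both cytokines against unstimulated gave 2880 and the highest other split 0 (1 of 10 as large), and both cytokines against IFN-gamma gave 0 in all 10. For lists by camera at the preset correlation, the real splits gave 17, 19 and 6 and the highest others 20, 21 and 17, with 4, 4 and 8 of 10 splits as large. Among the 3 other splits that part all 3 numbers, the most lists were 20, 21 and 9, and no gene was called with the block. In 40 simulations of unchanged groups, where genes vary independently, camera called at most 1 list. Every other split mixes both groups on each side, so it keeps part of the real difference and adds the rest to the spread. Such splits therefore show neither how many genes nor how many lists would be called without a difference. List counts at the preset correlation do not set the real groups apart from these mixed splits.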
